A study of Homo sapiens with 18 samples.

How the data were processed

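The study holds RNA from 3 human AML cell lines, MOLM13 (12 h), MV411 and U937 (24 h each), treated with 10 µM 3-HF or DMSO, with 3 libraries in each of 6 groups. Per the labels, RNA was taken with TRIZOL and libraries were made with a stranded TruSeq mRNA kit. The deposited file holds raw counts per gene symbol, and the submitters' processing notes name FastQC, HISAT2 2.1.0, SAMtools 1.9, HTSeq 0.11.2 and the hg19 build without giving the strand setting of the counting step, so values of antisense genes are uncertain. The table has 38320 lines, 1 of them with a blank symbol and 0 counts, which was dropped, and 38319 genes were kept. Its 18 columns were all used. The column letters T and U were read as treated (3-HF) and untreated (DMSO), an inference from the letters.

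Libraries had 8.60 to 10.2 M counts. Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (minimum count 10), robust quasi-likelihood fits and a prior count of 0.125 for fitted log2 fold changes. Each line was fitted on its own 6 libraries, 3-HF against DMSO, with a two-sided test and Benjamini-Hochberg adjustment over the genes tested, at 0.05. Differences of the 3-HF effect between lines were tested as contrasts in a fit of all 18 libraries with 6 group means. Counts of large changes used a log2 fold change of at least 1. Errors of log2 fold changes are SE, and errors of CPM are SD of 3 libraries. Folds against a group at 0 used a floor of 3 counts over the group. Overlap between lines was set against the number expected for independent lists. These choices, the gene lists and the rule for named genes were made before the data were examined.

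The 32 gene lists were written from general knowledge: NHEJ factors, homologous recombination and Fanconi factors, checkpoint signalling, p53 targets, MLL fusion targets, MLL fusion cofactors, MYC and ribosome biogenesis, G2/M, G1/S, the BCL2 family, monocyte maturation, myeloid progenitor and granule genes, interferon response, NF-kB, aryl hydrocarbon receptor targets, NRF2, ATF4, the ER unfolded protein response, heat shock, cholesterol synthesis, hypoxia and glycolysis, mitochondrially encoded genes, nuclear oxidative phosphorylation, lysosome and autophagy, FLT3 and STAT5 output, MAPK output, metallothioneins, and markers of T, B, erythroid, epithelial and fibroblast cells. Lists with at least 3 tested members were tested with fry (limma 3.58.1), adjusted over lists, and with camera at a preset correlation of 0.01 and with an estimated correlation. Members were also adjusted over the list alone. Named genes are a fixed set, the members of each list with the smallest p in that line, and the largest changes. These changes were the 8 largest increases and decreases per line. They were taken among called genes with a mean of at least 1 CPM and no overlap between groups. RIGI was found under an older symbol, and BOP1 and MRC1 are absent from the table.

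Whether libraries with the same replicate number belong together was checked from the correlation across genes of their deviations from the group mean. In U937 same-number pairs gave r = 0.52, 0.41 and 0.48 and the other pairs 0.01 or less, so values with this block are given beside U937 results that it changes. In MOLM13 same-number pairs gave 0.11, -0.20 and 0.16, and in MV411 0.05, -0.20 and 0.38.

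The pipeline was tested on simulated data with 200 changed genes. Of genes changed 2-fold it recovered 83.3% in MOLM13, 55.4% in MV411, 78.1% in U937 and 47.7% for the difference of the MLL-rearranged mean from U937, and of genes changed 4-fold 96.9%, 98.5%, 96.9% and 77.0%. Of genes changed 1.5-fold it recovered 50.0%, 6.06%, 20.9% and 10.6%. False calls made up 7.41%, 7.14%, 10.6% and 6.59% of the calls. The fry test called 0 of 20 unchanged lists in each line. The simulated genes varied independently, with no effect shared by libraries of the same replicate number. In the data 55.9% of genes were called in MOLM13 and 54.3% in MV411, so these rates may not carry over.

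Alternatives were a single fit of all libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, no filter, a filter of 1 CPM in 3 libraries, an adjusted p of 0.01 for the overlap, and leaving out each library. Upper quartile scaling for the lists, a restriction of the differences to genes past the filter in each line, and the overlap without MV411 DMSO 1 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Read-level data and transcript isoforms were not analysed here.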

Results

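RNA was sequenced from 3 human acute myeloid leukemia (AML) cell lines grown with 10 µM 3-hydroxyflavone (3-HF), a plant-type flavonol, or with its solvent DMSO. MOLM13 and MV411 are lines with a rearrangement of the MLL gene (KMT2A), a chromatin regulator whose fusions drive a class of acute leukemia, and U937 is a monocytic line used here as the comparison without one. MOLM13 was treated for 12 h, and MV411 and U937 for 24 h, so that treatment time and line cannot be told apart in MOLM13. Each of the 6 groups had 3 libraries, 18 in all, with total gene counts of 8.60 to 10.2 M per library. The range was 8.64 to 9.99 M in MOLM13, 9.02 to 10.2 M in MV411 and 8.60 to 10.1 M in U937. Columns marked T were read as 3-HF and those marked U as DMSO, an inference from the letters, and every direction would turn round if it were wrong. The libraries hold PCR-amplified reads without molecular identifiers, so counting intervals and floors cover counting error only. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

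Libraries of a group correlated at Pearson r = 0.980 or more across genes, which are not independent replicates, with MV411 DMSO 1 as the exception. This library reached r = 0.964 and 0.943 with the other MV411 DMSO libraries, which correlated at 0.993 with each other. The share of counts from mitochondrially encoded genes was 4.57 ± 0.41% (SD, n = 3) with DMSO and 5.81 ± 0.07% with 3-HF in MOLM13, 3.63 ± 0.45% and 4.56 ± 0.20% in MV411, and 5.14 ± 0.35% and 5.58 ± 0.55% in U937.

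The first question was how a short exposure to 3-HF changes expression in the MLL-rearranged line MOLM13, with the repair kinase named in the series title as the gene of interest. PRKDC, the catalytic subunit of the DNA-dependent protein kinase that joins broken DNA ends, fell 2.02-fold after 12 h, from 476 ± 85.8 to 236 ± 19.8 CPM (SD, n = 3 per group), a log2 fold change of -1.01 ± 0.13 (SE). MYC, the transcription factor that drives growth genes, fell 8.78-fold, from 895 ± 55.2 to 102 ± 7.56 CPM. CSF1R, the receptor that supports monocytes and macrophages, rose 7.33-fold, and BMF, a pro-apoptotic BCL2 family member, rose 5.26-fold. Among 12226 genes tested, 3337 rose and 3503 fell, 1130 and 1241 of them by at least 2-fold. In 7572 genes, 61.9%, every 3-HF library lay on one side of every DMSO library, where chance gives 10%. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 4.3e-05 for PRKDC, 6.1e-09 for MYC, 6.1e-09 for CSF1R and 7.1e-09 for BMF. With upper quartile scaling, which moved the median log2 change of all genes from 0.02 to 0.18, 4438 genes rose and 2689 fell, so that the higher share went from 48.8% to 62.3%.

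Among called genes with a mean of at least 1 CPM and no overlap between groups, the largest increases in MOLM13 were those of LINC02371, a long noncoding RNA with 1 count in DMSO and 69 in 3-HF (count ratio 60.7, counting interval 10.5 to 2434), and of the cyclin-dependent kinase inhibitor CDKN1C with 3 and 154 counts (count ratio 45.2, counting interval 15.2 to 222). PROC, which encodes the anticoagulant protein C (4.99 ± 0.35), the chloride channel gene CLIC3 (4.46 ± 0.55), the peptide hormone gene ENHO (4.33 ± 0.42) and the serine dehydratase gene SDS (4.29 ± 0.26) followed, as log2 fold changes ± SE. The growth factor gene BMP10 (3.54 ± 0.41) and KLHDC8B (3.49 ± 0.45) rose next. Of the largest decreases over the same genes, GPR3, a receptor that raises cyclic AMP, went from 70 counts to 1 (count ratio 0.0126, counting interval 0.000314 to 0.0724). DDN (-5.18 ± 0.28), the cell fusion gene OCSTAMP (-4.69 ± 0.24), RGS16, a brake on G protein signalling (-4.67 ± 0.34), and the AP-1 subunit FOSL1 (-4.08 ± 0.21) fell most after it. SH2D4A (-4.00 ± 0.48), the chromatin factor BEND3 (-3.99 ± 0.39) and the fatty acid receptor GPR84 (-3.99 ± 0.27) complete the 8.

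More DNA repair genes fell than rose in MOLM13, where 55.9% of all genes tested were called, 3503 lower and 3337 higher. Of 17 NHEJ factors, the end-joining proteins that PRKDC works with, 7 fell and 3 rose (7 and 3 adjusted over the list alone), with a median of -0.04 and a fry adjusted p = 0.00278, lost at adjusted p = 0.710 with an estimated correlation, 0.00146 to 0.710 over the alternatives. Both Ku subunits that load PRKDC onto DNA ends fell, XRCC5 (-0.54 ± 0.08) and XRCC6 (-0.56 ± 0.10), while the nuclease gene DCLRE1C rose by 0.55 ± 0.12. With upper quartile scaling the NHEJ median was 0.12 (adjusted p = 0.648). The share of NHEJ factors called lay close to that of all genes, and camera with the preset correlation gave adjusted p = 0.681. Of 30 homologous recombination and Fanconi genes, 17 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.54 and a fry adjusted p = 7.7e-05, lost at adjusted p = 0.113 with an estimated correlation, 2.1e-05 to 0.113 over the alternatives. The end resection factor RBBP8 (-1.02 ± 0.13) and the BRCA2 partner PALB2 (-1.10 ± 0.15) were lower. Of 20 checkpoint genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.32 and a fry adjusted p = 5.8e-05, lost at adjusted p = 0.113 with an estimated correlation, 2.4e-05 to 0.113 over the alternatives. CDC25A, a phosphatase that activates cyclin-dependent kinases, fell by 2.53 ± 0.14, and the replication checkpoint proteins CLSPN (-1.07 ± 0.11) and TIPIN (-1.81 ± 0.19) fell. The p53 target list was not called: 10 rose and 4 fell (9 and 4 adjusted over the list alone) of 27, with a median of 0.01 and a fry adjusted p = 0.0750. The p53 cofactor gene TP53INP1 (2.07 ± 0.22) and the cyclin gene CCNG1 (1.03 ± 0.11) rose. The nuclease gene AEN (-1.85 ± 0.11) and the cell cycle inhibitor CDKN1A (-0.45 ± 0.09) fell, and MDM2, which degrades p53, stood at 0.01 ± 0.10 (adjusted p = 0.909). That list was called higher with upper quartile scaling (adjusted p = 0.00151) and without 3-HF 1 (0.0414).

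All 27 tested MYC and ribosome biogenesis genes fell, also adjusted over the list alone, with a median of -1.82, a fry adjusted p = 3.7e-06 and adjusted p = 0.00449 with an estimated correlation. The polyamine enzyme SRM (-2.99 ± 0.13) and the nucleolar proteins NOLC1 (-2.30 ± 0.10) and RRP12 (-2.22 ± 0.10) were among them. Of 41 G1/S and DNA replication genes, 38 fell and 0 rose (38 and 0 adjusted over the list alone), with a median of -1.04, a fry adjusted p = 1.9e-05 and adjusted p = 0.0125 with an estimated correlation. E2F1, which switches on S phase genes, fell by 2.02 ± 0.12. The replication helicase component CDC45 (-1.87 ± 0.10) and the ribonucleotide reductase subunit RRM2 (-1.75 ± 0.10) fell too. Mitotic genes moved less: of 30 G2/M genes, 8 fell and 3 rose (7 and 3 adjusted over the list alone), with a median of -0.05 and a fry adjusted p = 0.183, although the call was made without DMSO 3 (0.0211). The mitotic cyclin CCNB1 (-0.59 ± 0.08) and the kinase PLK1 (-0.47 ± 0.09) fell, and the kinetochore protein CENPF rose (0.47 ± 0.10), a call lost with all libraries in a single fit (adjusted p = 0.0537). The proliferation marker MKI67 stood at -0.05 ± 0.09 (adjusted p = 0.654).

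MLL fusion targets, the genes that MLL fusions keep active, rose in 7 and fell in 2 (7 and 2 adjusted over the list alone) of 17, with a median of 0.29 and a fry adjusted p = 0.0254, lost at adjusted p = 0.615 with an estimated correlation, 0.00933 to 0.615 over the alternatives. The receptor kinase FLT3 rose by 1.11 ± 0.10 and the homeobox factor MEIS1 by 0.67 ± 0.13, and RUNX1 fell by 0.59 ± 0.09. HOXA9, the homeobox partner of MEIS1, stood at 0.11 ± 0.10 (adjusted p = 0.330, called at 0.28 with upper quartile scaling). Of 19 cofactors of MLL fusions, 7 fell and 2 rose (6 and 2 adjusted over the list alone), with a median of -0.15 and a fry adjusted p = 0.0241, lost at adjusted p = 0.710 with an estimated correlation, 0.0135 to 0.916 over the alternatives, and the median was 0.02 with upper quartile scaling. The histone methyltransferase DOT1L (-1.02 ± 0.10) and the scaffold protein MEN1 (-0.61 ± 0.11) were lower. The BCL2 family was split, 3 fell and 3 rose (3 and 3 adjusted over the list alone) of 14, with a median of 0.00, and its fry call (up, adjusted p = 0.00875) was lost at adjusted p = 0.564 with an estimated correlation, 1.6e-04 to 0.564 over the alternatives. The target call ended without DMSO 1 (0.0643), 3-HF 1 (0.0729), 3-HF 2 (0.0584) or 3-HF 3 (0.0788), adjusted p in brackets. The cofactor call ended without DMSO 1 (0.0643), DMSO 2 (0.0566), 3-HF 2 (0.0758) or 3-HF 3 (0.0854). Leaving out DMSO 1 (0.0657) or DMSO 2 (0.0755) ended the BCL2 call.

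Of 18 monocyte and macrophage genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.75, a fry adjusted p = 3.3e-05 and adjusted p = 0.0369 with an estimated correlation. Besides CSF1R (2.87 ± 0.11), the costimulatory ligand CD86 (2.66 ± 0.26) and the scavenger receptor CD36 (1.58 ± 0.12) rose, the integrin ITGAM stood at 0.23 ± 0.16 (adjusted p = 0.241), and CD14 lay under the count filter. Interferon response genes rose in 13 and fell in 1 of 19 (14 and 1 adjusted over the list alone), with a median of 1.31, a fry adjusted p = 3.3e-05 and adjusted p = 0.0369 with an estimated correlation. The regulators IRF7 (1.85 ± 0.12) and STAT2 (1.88 ± 0.13) and the antiviral factor SAMD9L (2.26 ± 0.25) were higher. Of 13 myeloid progenitor and granule genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.13 and a fry adjusted p = 0.00359, lost at adjusted p = 0.252 with an estimated correlation, 0.00460 to 0.252 over the alternatives. GATA2, a transcription factor of blood stem and progenitor cells, fell by 2.55 ± 0.12, and the granule protease PRTN3 fell by 0.92 ± 0.17. NF-kB and inflammatory genes went both ways, 6 rose and 5 fell (6 and 5 adjusted over the list alone) of 14, with a median of 0.14 and a fry adjusted p = 0.0730, although the list was called higher without 3-HF 3 (0.0462). TNFAIP2 rose by 2.00 ± 0.11 and the chemokine CCL3 fell by 1.92 ± 0.25.

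Growth signalling outputs fell in MOLM13. Of 17 MAPK output and immediate early genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -1.83, a fry adjusted p = 2.3e-05 and adjusted p = 0.0290 with an estimated correlation. The ETS factors ETV4 (-3.61 ± 0.24) and ETV5 (-3.26 ± 0.20) and the MAPK phosphatase DUSP2 (-2.49 ± 0.14) were lower. Of 11 FLT3 and STAT5 output genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -1.28 and a fry adjusted p = 5.8e-05, lost at adjusted p = 0.0511 with an estimated correlation, 5.0e-07 to 0.0511 over the alternatives. The cytokine feedback inhibitor CISH (-2.08 ± 0.11), the survival kinase PIM1 (-1.97 ± 0.15) and the cyclin CCND3 (-1.28 ± 0.09) fell.

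Protein folding genes fell as well. Of 15 heat shock genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -1.61, a fry adjusted p = 3.7e-06 and adjusted p = 0.0125 with an estimated correlation. The chaperone HSPA8 (-2.47 ± 0.11) and the cochaperone FKBP4 (-2.42 ± 0.10) were lower. Of 19 genes of the ER unfolded protein response, 16 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -0.84, a fry adjusted p = 2.9e-05 and adjusted p = 0.0369 with an estimated correlation, among them the chaperone HSPA5 (-2.67 ± 0.11) and the transcription factor XBP1 (-2.40 ± 0.09). Of 26 ATF4 genes, 17 fell and 3 rose (17 and 3 adjusted over the list alone), with a median of -0.57 and a fry adjusted p = 3.3e-05, lost at adjusted p = 0.0793 with an estimated correlation, 2.6e-05 to 0.0793 over the alternatives. The amino acid transporter SLC7A5 (-3.53 ± 0.13), the pseudokinase TRIB3 (-1.88 ± 0.11) and the serine synthesis enzyme PSAT1 (-2.02 ± 0.14) fell. NRF2 oxidative stress genes were not called, 6 fell and 5 rose (6 and 5 adjusted over the list alone) of 21, with a median of -0.01 and a fry adjusted p = 0.193. Heme oxygenase HMOX1 rose by 1.92 ± 0.30 and peroxiredoxin PRDX1 fell by 1.17 ± 0.10. Of 4 aryl hydrocarbon receptor targets, 2 fell and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.40 and a fry adjusted p = 0.0273, lost at adjusted p = 0.710 with an estimated correlation, 0.00990 to 0.710 over the alternatives and also without DMSO 3 (0.0512), 3-HF 1 (0.0729), 3-HF 2 (0.0758) or 3-HF 3 (0.0854). The cytochrome P450 gene CYP1B1 fell by 0.81 ± 0.15, and CYP1A1 lay under the count filter. Of 6 metallothionein and zinc genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.23 and a fry adjusted p = 0.0241, lost at adjusted p = 0.564 with an estimated correlation, 0.00764 to 0.564 over the alternatives and also without DMSO 1 (0.0757), DMSO 2 (0.0651), 3-HF 2 (0.0758) or 3-HF 3 (0.0788). The metal-binding MT2A rose by 1.68 ± 0.13.

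Of 23 cholesterol synthesis genes, 18 fell and 0 rose (19 and 1 adjusted over the list alone), with a median of -0.75, a fry adjusted p = 2.9e-05 and adjusted p = 0.0303 with an estimated correlation, among them the reductase DHCR7 (-1.93 ± 0.11). Of 26 hypoxia and glycolysis genes, 14 fell and 4 rose (14 and 4 adjusted over the list alone), with a median of -0.42 and a fry adjusted p = 0.00141, lost at adjusted p = 0.330 with an estimated correlation, 9.8e-04 to 0.330 over the alternatives. Lactate dehydrogenase LDHA fell by 1.96 ± 0.10, and BNIP3L, which marks mitochondria for removal, rose by 1.53 ± 0.10. Of 25 nuclear oxidative phosphorylation genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.32 and a fry adjusted p = 0.0379, lost at adjusted p = 0.710 with an estimated correlation, 0.0228 to 0.710 over the alternatives and also without DMSO 1 (0.103), DMSO 3 (0.0776), 3-HF 1 (0.109), 3-HF 2 (0.0758) or 3-HF 3 (0.0860). The complex III subunit CYC1 was lower (-0.84 ± 0.11). Of 13 mitochondrially encoded genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of -0.02, a mean of 0.08 and a fry direction of up (adjusted p = 0.193), called without DMSO 1 (0.0307). MT-ND3, a complex I subunit, rose by 0.44 ± 0.11 (adjusted p = 0.0583 with all libraries in a single fit), in the same libraries whose mitochondrial share went from 4.57% to 5.81%. Of 20 lysosome and autophagy genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.44 and a fry adjusted p = 1.1e-04, lost at adjusted p = 0.0780 with an estimated correlation, 2.8e-05 to 0.0780 over the alternatives. The lysosomal protease CTSB (0.94 ± 0.09) and the autophagy receptor SQSTM1 (0.90 ± 0.09) were higher.

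In MOLM13, fry called 22 of 27 lists, 6 up and 16 down, and 8 of these calls held with an estimated correlation. The fry test asks whether the genes of a set move, on balance, one way, and does not compare the set with other genes. Camera, at the preset or an estimated correlation, does compare the set with all other genes. At the preset correlation 14 of the 22 calls held. A call lost at both settings can be a shift shared with other genes. A call lost only with an estimated correlation is no sign of such a shift. The FLT3 and STAT5 list, for example, had a camera adjusted p = 5.0e-07 at the preset correlation and 0.0511 with an estimated one. Of markers of other cell types, the collagen gene COL1A1 of fibroblasts rose by 3.17 ± 0.40 as the only member of its list tested, and no T cell, erythroid or epithelial marker was tested. Under upper quartile scaling fry also called NF-kB genes (adjusted p = 0.00764) and mitochondrially encoded genes (0.0288, at a median of 0.14), and the calls for aryl hydrocarbon receptor targets (0.123) and oxidative phosphorylation genes (0.188) ended.

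The same question was asked of MV411, the other MLL-rearranged line, after 24 h. PRKDC fell 4.72-fold, from 1117 ± 358 to 237 ± 11.4 CPM (SD, n = 3 per group), and MYC fell 2.63-fold, from 546 ± 52.95 to 208 ± 3.96 CPM. MKI67, a protein of cycling cells, fell 12.7-fold, and the integrin ITGAM, a surface marker of maturing monocytes, rose 6.13-fold. Of 12981 genes tested, 3483 rose and 3565 fell, 2123 and 1940 of them by at least 2-fold, and in 8305 genes, 64.0%, the groups did not overlap, where chance gives 10%. edgeR's quasi-likelihood test gave adjusted p = 2.7e-04 for PRKDC, 1.0e-04 for MYC, 7.2e-05 for MKI67 and 3.3e-05 for ITGAM. With upper quartile scaling, which moved the median of all genes from -0.02 to 0.16, 4225 genes rose and 2808 fell, a higher share of 60.1% in place of 49.4%. Without DMSO 1, the library that stands apart, 4751 genes rose and 4711 fell.

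Among called genes with a mean of at least 1 CPM and no overlap between groups, the 8 largest increases in MV411 were of genes with 0 counts in all DMSO libraries, taken against a floor of 3 counts over the group. The ferritin receptor SCARA5 was at least 76.5-fold higher, the matrix protein TINAGL1 59.7, the semaphorin receptor NRP2 34.9, NLRP4 33.6, the collagen chain COL6A3 32.7, FBXO39 31.4, the Toll-like receptor TLR10 27.9 and the disulfide isomerase PDIA2 25.7, each as at least that fold. Among the decreases, the oxysterol-binding OSBPL3 went from 57 counts to 0, at least 19.96-fold lower. The monocyte chemokine CCL2 (-6.82 ± 0.26), the ETS factor ETV4 (-6.42 ± 0.24) and the immediate early factor EGR3 (-5.49 ± 0.52) were the members with more counts among the 8 largest decreases. RAB3IL1 went from 104 counts to 1 (count ratio 0.00915, counting interval 0.000230 to 0.0521) and ACTL8 from 90 to 1 (count ratio 0.0106, counting interval 0.000265 to 0.0605). CSRP3-AS1 (136 to 1, count ratio 0.00700, counting interval 0.000176 to 0.0397) is an antisense gene and PLA2G12AP1 (60 to 1, count ratio 0.0159, counting interval 0.000395 to 0.0918) a pseudogene, and both are uncertain where reads of the partner strand or parent gene could be counted to them.

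In MV411, of 17 NHEJ factors 8 fell and 5 rose (8 and 5 adjusted over the list alone), with a median of -0.45 and a fry adjusted p = 5.4e-04, lost at adjusted p = 0.396 with an estimated correlation, 7.0e-04 to 0.396 over the alternatives. XRCC5 (-0.90 ± 0.11), XRCC6 (-1.39 ± 0.15) and the ligase partner XRCC4 (-1.36 ± 0.20) fell with PRKDC (-2.24 ± 0.25). Of 31 homologous recombination and Fanconi genes, 25 fell and 2 rose (25 and 2 adjusted over the list alone), with a median of -1.65 and a fry adjusted p = 1.6e-04, lost at adjusted p = 0.0508 with an estimated correlation, 5.4e-12 to 0.0508 over the alternatives. The tumor suppressor BRCA1 (-3.37 ± 0.20) and the Fanconi protein FANCI (-2.24 ± 0.11) fell. Of 20 checkpoint genes, 17 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -1.67, a fry adjusted p = 1.2e-05 and adjusted p = 0.0246 with an estimated correlation. The checkpoint kinase CHEK1 (-3.23 ± 0.14), CDC25A (-3.51 ± 0.15) and CLSPN (-3.86 ± 0.30) were lower. The p53 targets were not called, 7 fell and 4 rose (7 and 4 adjusted over the list alone) of 25, with a median of -0.22 and a fry adjusted p = 0.103, but were called lower without DMSO 1 (0.0117) or DMSO 3 (0.0490). TP53INP1 (4.95 ± 0.32) and BTG2, a brake on proliferation (1.26 ± 0.13), rose, and AEN (-2.78 ± 0.16) and CDKN1A (-1.23 ± 0.25) fell. MDM2 stood at -0.27 ± 0.13 (adjusted p = 0.121), and at -0.34 (adjusted p = 0.0143) without DMSO 1.

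Cell cycle genes fell throughout in MV411. All 29 tested G2/M genes fell, also adjusted over the list alone, with a median of -3.23, a fry adjusted p = 1.8e-05 and adjusted p = 0.0111 with an estimated correlation. The mitotic kinase CDK1 (-3.35 ± 0.15), CCNB1 (-3.56 ± 0.15) and the kinetochore protein NDC80 (-3.40 ± 0.15) were among them. All 41 G1/S genes fell, also adjusted over the list alone, with a median of -2.78, a fry adjusted p = 1.2e-05 and adjusted p = 0.0111 with an estimated correlation. The replication licensing factor CDC6 (-4.87 ± 0.14), RRM2 (-4.36 ± 0.16) and the helicase subunit MCM6 (-3.15 ± 0.13) fell. All 28 MYC and ribosome biogenesis genes fell, also adjusted over the list alone, with a median of -1.71 and a fry adjusted p = 1.3e-04, lost at adjusted p = 0.0508 with an estimated correlation, 2.7e-13 to 0.0508 over the alternatives. RRP12 (-1.54 ± 0.11) and the nucleolar GTPase GNL3 (-1.68 ± 0.11) fell.

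Of 14 MLL fusion targets in MV411, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.25 and a fry adjusted p = 0.0409, lost at adjusted p = 0.735 with an estimated correlation, 0.0146 to 0.735 over the alternatives and also without DMSO 2 (0.105), 3-HF 1 (0.125), 3-HF 2 (0.0755) or 3-HF 3 (0.116). FLT3 rose by 1.46 ± 0.15, RUNX2, a transcription factor of the runt family, by 1.02 ± 0.17 and MEIS1 by 0.67 ± 0.14. HOXA9 rose by 0.43 ± 0.12, a call that ended without DMSO 2 (adjusted p = 0.0583), 3-HF 1 (0.0799) or 3-HF 3 (0.0714). The MLL cofactors were not called, 7 fell and 0 rose (6 and 0 adjusted over the list alone) of 19, with a median of -0.39 and a fry adjusted p = 0.0559, but were without DMSO 1 (0.00630). The chromatin tether PSIP1 (-0.90 ± 0.16) and DOT1L (-0.60 ± 0.13) were lower. The BCL2 family, 2 rose and 1 fell (1 and 0 adjusted over the list alone) of 13, had a median of 0.01, and its fry call (up, adjusted p = 0.0289) was lost at adjusted p = 0.688 with an estimated correlation, 1.1e-04 to 0.688 over the alternatives and also without DMSO 2 (0.105), DMSO 3 (0.150), 3-HF 1 (0.0956), 3-HF 2 (0.0863) or 3-HF 3 (0.0803). BMF rose by 2.89 ± 0.13.

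Of 17 monocyte and macrophage genes in MV411, 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.28, a fry adjusted p = 3.0e-05 and adjusted p = 0.0347 with an estimated correlation. The integrins ITGAX (3.94 ± 0.13) and ITGAM (2.62 ± 0.18) and CSF1R (2.52 ± 0.13) were higher, and CD14 lay under the count filter. Of 27 interferon response genes, 20 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.77, a fry adjusted p = 3.0e-05 and adjusted p = 0.0347 with an estimated correlation. STAT2 rose by 2.90 ± 0.17 and the antiviral enzymes RSAD2 and OAS1 by 3.36 ± 0.26 and 3.33 ± 0.28. Myeloid progenitor genes were not called, 5 rose and 2 fell (5 and 2 adjusted over the list alone) of 13, with a median of 0.18 and a fry adjusted p = 0.102, but were called higher without DMSO 1 (0.0110). The stem cell factor receptor KIT rose by 3.00 ± 0.28 and myeloperoxidase MPO fell by 1.29 ± 0.23. NF-kB genes went both ways, 6 fell and 6 rose (6 and 7 adjusted over the list alone) of 15, with a median of 0.07, a mean of -0.17 and a fry adjusted p = 0.529. The signalling adaptor TRAF1 rose by 3.00 ± 0.19, and CCL2 fell by 6.82 ± 0.26.

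Of 20 MAPK output genes in MV411, 11 fell and 5 rose (11 and 5 adjusted over the list alone), with a median of -1.73 and a fry adjusted p = 3.0e-05, lost at adjusted p = 0.0564 with an estimated correlation, 3.4e-05 to 0.0564 over the alternatives. ETV4 (-6.42 ± 0.24), ETV5 (-3.31 ± 0.25), the ERK phosphatase DUSP6 (-2.20 ± 0.15) and the receptor signalling inhibitor SPRY2 (-2.09 ± 0.16) were lower. Of 12 FLT3 and STAT5 output genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -1.001 and a fry adjusted p = 1.9e-04, lost at adjusted p = 0.115 with an estimated correlation, 1.1e-05 to 0.115 over the alternatives. PIM1 (-3.53 ± 0.14), the cytokine OSM (-2.82 ± 0.17) and CISH (-1.96 ± 0.16) fell. Of 15 heat shock genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -1.99 and a fry adjusted p = 5.8e-05, lost at adjusted p = 0.0508 with an estimated correlation, 2.3e-11 to 0.0508 over the alternatives. HSPA8 (-3.46 ± 0.18) and the chaperone HSP90AA1 (-2.56 ± 0.14) fell. Of 19 ER unfolded protein response genes, 12 fell and 2 rose (12 and 2 adjusted over the list alone), with a median of -0.94 and a fry adjusted p = 2.7e-05, lost at adjusted p = 0.0564 with an estimated correlation, 1.0e-05 to 0.0564 over the alternatives. XBP1 (-1.74 ± 0.13) and HSPA5 (-1.36 ± 0.13) were lower. Of 27 ATF4 genes, 22 fell and 2 rose (22 and 3 adjusted over the list alone), with a median of -1.29 and a fry adjusted p = 1.6e-04, lost at adjusted p = 0.104 with an estimated correlation, 3.0e-08 to 0.104 over the alternatives. SLC7A5 (-3.15 ± 0.15) and PSAT1 (-2.82 ± 0.13) fell.

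NRF2 genes, 7 rose and 6 fell (8 and 6 adjusted over the list alone) of 19 in MV411, had a median of 0.28 and a fry adjusted p = 0.0409, lost at adjusted p = 0.735 with an estimated correlation, 0.00776 to 0.735 over the alternatives and also without DMSO 2 (0.127), DMSO 3 (0.151), 3-HF 1 (0.173), 3-HF 2 (0.144) or 3-HF 3 (0.0929). HMOX1 rose by 3.93 ± 0.22. Of 5 aryl hydrocarbon receptor targets, 3 fell and 0 rose (3 and 0 adjusted over the list alone), with a median of -0.66 and a fry adjusted p = 0.00944, lost at adjusted p = 0.540 with an estimated correlation, 0.00785 to 0.540 over the alternatives and also without DMSO 2 (0.050002). CYP1A1, the classic target of that receptor, fell by 1.65 ± 0.34, and CYP1B1 stood at -0.18 ± 0.35 (adjusted p = 0.699). Of 6 metallothionein and zinc genes, 1 fell and 0 rose (1 and 0 adjusted over the list alone), with a median of -0.06 and a fry adjusted p = 0.470. Of 23 cholesterol synthesis genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.49 and a fry adjusted p = 1.7e-04, lost at adjusted p = 0.129 with an estimated correlation, 1.7e-04 to 0.129 over the alternatives, with DHCR7 at -2.54 ± 0.20. Of 26 hypoxia and glycolysis genes, 11 fell and 5 rose (11 and 5 adjusted over the list alone), with a median of -0.41 and a fry adjusted p = 5.4e-04, lost at adjusted p = 0.244 with an estimated correlation, 1.6e-04 to 0.244 over the alternatives, with LDHA at -2.36 ± 0.15. Nuclear oxidative phosphorylation genes were not called, 12 fell and 1 rose (12 and 1 adjusted over the list alone) of 26, with a median of -0.64 and a fry adjusted p = 0.102, but were without DMSO 1 (0.0291). Of 13 mitochondrially encoded genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of -0.09, a mean of 0.04 and a fry direction of up (adjusted p = 0.238), beside a mitochondrial share of 3.63% with DMSO and 4.56% with 3-HF. Of 18 lysosome and autophagy genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.60 and a fry adjusted p = 0.00383, lost at adjusted p = 0.475 with an estimated correlation, 3.7e-04 to 0.475 over the alternatives. The autophagy protein GABARAPL1 rose by 2.81 ± 0.19. In MV411 fry called 20 of 27 lists, 6 up and 14 down, and 5 of these calls held with an estimated correlation. Of markers of other cell types, the B cell receptor component CD79A rose by 1.64 ± 0.26. In MV411, fry also called myeloid progenitor genes (adjusted p = 0.0220), NF-kB genes (0.0182) and mitochondrially encoded genes (0.0182, at a median of 0.09) under upper quartile scaling.

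U937 served as the comparison line without an MLL rearrangement. As the only such line, it cannot show how far the response to 3-HF depends on the rearrangement. TFRC, the transferrin receptor that takes up iron, rose 2.14-fold after 24 h, from 136 ± 27.2 to 292 ± 38.5 CPM (SD, n = 3 per group), and PSAT1 rose 1.73-fold. The chemokine CCL2 fell 3.49-fold, and the glycolysis regulator PFKFB4 (-1.82 ± 0.25 on the log2 scale) and the creatine transporter SLC6A8 (-1.91 ± 0.29) fell. PRKDC stood at 0.21 ± 0.19 (adjusted p = 0.925, from 480.4 ± 88.4 to 556 ± 129 CPM) and MYC at 0.26 ± 0.15 (adjusted p = 0.876). With the replicate number as a block, MYC rose by 0.26 ± 0.07 (adjusted p = 0.00587), and PRKDC stood at 0.20 ± 0.08 (adjusted p = 0.0815). Of 12520 genes tested, 2 rose and 12 fell by edgeR's quasi-likelihood test, 1 and 12 of them by at least 2-fold, with 764 genes at an unadjusted p under 0.05 where 626 are expected by chance. In 1357 genes, 10.8%, the groups did not overlap, where chance gives 10% for independent libraries. Same-number libraries of U937 deviated together, which would lower that chance share, so the 10% is not an exact reference here. For 10949 genes, 87.5%, the 95% interval of the fold change lay within 2-fold, against 60.6% in MOLM13 and 40.4% in MV411.

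The remaining calls of U937 included several copies that share reads. NCF1 (-1.65 ± 0.27), a subunit of the phagocyte oxidase, and its near-identical copies NCF1B (-2.38 ± 0.31) and NCF1C (-2.01 ± 0.31) fell, as did the histone genes H2AC6 (-1.72 ± 0.22), H2BC11 (-2.05 ± 0.34) and H2BC12 (-1.19 ± 0.21), and reads of such copies cannot be assigned with certainty. MIR210HG, the host transcript of a hypoxia-induced microRNA, fell by 3.43 ± 0.40. The copies RASA4B (-1.67 ± 0.30) and HSPA7 (-1.42 ± 0.23), named with H2BC12 only because they complete the 14 calls, also fell. PSAT1 lost its call whichever library was left out (adjusted p of 0.0819 to 0.142) and with RLE scaling (0.0565), and TFRC lost its call without DMSO 2 (0.0917). H2BC11 lost it without DMSO 2 (0.111), 3-HF 1 (0.0819) or 3-HF 2 (0.0947), NCF1C without DMSO 2 (0.0807) or 3-HF 3 (0.0635), and NCF1 without DMSO 2, 3-HF 1 or 3-HF 3 (0.0692 to 0.0909). Without DMSO 2 the count was 0 higher and 6 lower, without 3-HF 1 it was 7 lower, and without DMSO 1, 3-HF 2 or 3-HF 3 it was 1 higher.

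Libraries of U937 with the same replicate number deviated together, at r = 0.52, 0.41 and 0.48 across genes. With the replicate number as a block, 585 genes rose and 794 fell, 25 and 24 of them by at least 2-fold, with a median absolute log2 change of 0.36 over the called genes, and all 14 calls made without the block were among them. With the block, TFRC (1.10 ± 0.07), SLC7A5 (0.55 ± 0.07) and the stress sensor SESN2 (0.91 ± 0.11) rose, and LDHA (-0.84 ± 0.07), PLK1 (-0.71 ± 0.07) and CCNB1 (-0.67 ± 0.07) fell. The blocked fit compares only 3 pairs of libraries, so these errors lean on the spread shared across genes. Its calls are less firm than their errors make them look. Other settings that moved the count were DESeq2 with 11 higher and 31 lower, all 18 libraries in a single fit with 9 and 32, and no low-count filter with 16 and 40.

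Fry called few gene lists in U937, and more of their members were called with the replicate block. ATF4 genes had 1 of 24 higher (13 adjusted over the list alone), with a median of 0.38 and a fry adjusted p = 0.0360, lost at adjusted p = 0.0710 with an estimated correlation, 2.6e-19 to 0.152 over the alternatives. With the block 19 of these rose. Heat shock genes had 0 of 14 called (1 lower adjusted over the list alone), with a median of -0.29 and a fry adjusted p = 0.0360, lost at adjusted p = 0.0710 with an estimated correlation, 6.0e-08 to 0.152 over the alternatives. Leaving out any of the 6 libraries ended both calls, at adjusted p of 0.0628 or more. Monocyte genes had 1 of 17 lower, NCF1, also adjusted over the list alone (2 lower with the block), with a median of -0.24 and a fry adjusted p = 0.0459, lost at adjusted p = 0.0710 with an estimated correlation, 7.4e-04 to 0.152 over the alternatives and without DMSO 1 (0.0679), DMSO 2 (0.104), DMSO 3 (0.132), 3-HF 1 (0.112) or 3-HF 3 (0.152). G1/S genes had 0 of 41 called by edgeR, also adjusted over the list alone, with a median of -0.15 and a fry adjusted p = 0.00290, lost at adjusted p = 0.0710 with an estimated correlation, 3.6e-06 to 0.0710 over the alternatives. With the block 11 of these fell, as did 9 of the heat shock genes, 26 of 29 G2/M genes and 16 of 26 hypoxia and glycolysis genes. The G2/M list, with a median of -0.43, 0 members called and 16 lower adjusted over the list alone, had a fry adjusted p = 0.0650 and 0.0387 with the block. Hypoxia and glycolysis genes, with 1 lower (15 lower and 1 higher adjusted over the list alone) and a median of -0.43, had a fry adjusted p = 0.0650 and 0.141 with the block. Over the alternatives, camera among them, the adjusted p went from 1.3e-23 to 0.209 for G2/M and from 3.7e-20 to 0.209 for hypoxia genes. Of 28 lists tested, fry called these 4, 0 of them with an estimated correlation, where camera with a preset correlation called 11. DNA repair and p53 lists had 0 members called in U937 (1 checkpoint gene lower and 1 p53 target higher adjusted over the list alone), with medians of -0.02 for NHEJ (adjusted p = 0.871), -0.03 for homologous recombination (0.871), -0.10 for checkpoint genes (0.359) and -0.02 for p53 targets (0.553). With the block, 1 NHEJ factor rose and 2 fell, 1 p53 target rose and 2 fell, 2 checkpoint genes fell, and 0 homologous recombination genes were called, and fry called none of these 4 lists (lowest adjusted p = 0.159). The monocyte (0.0817) and heat shock (0.0544) calls also ended under upper quartile scaling.

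Other lists were not called in U937. MLL fusion targets had a median of 0.20 (fry adjusted p = 0.174, 0 called and 1 higher adjusted over the list alone) and MLL cofactors 0.06 (0.844). MYC and ribosome biogenesis genes stood at -0.07 (0.617), the BCL2 family at -0.02 (0.575), myeloid progenitor genes at 0.06 (0.805) and interferon genes at 0.00 (0.797), by fry adjusted p. NF-kB genes, with CCL2 lower, had a median of -0.07 (fry adjusted p = 0.170). The 3 aryl hydrocarbon receptor targets stood at -0.08 (0.0650, 1 lower adjusted over the list alone), and were called without 3-HF 2 at a median of 0.07 (adjusted p = 0.0121), with CYP1A1 under the count filter and CYP1B1 listed at 0. NRF2 genes had a median of -0.16 (0.170), ER unfolded protein response genes -0.07 (0.615) and cholesterol synthesis genes -0.05 (0.422), by fry. Mitochondrially encoded genes stood at 0.05 (0.422), nuclear oxidative phosphorylation genes at -0.10 (0.575) and lysosome genes at -0.01 (0.422), by fry. FLT3 and STAT5 output genes had a median of -0.04 (0.359), MAPK output genes -0.09 (0.542), metallothioneins 0.01 (0.871) and B cell markers -0.02 (0.575), by fry. With the block fry called none of the lists in this paragraph (lowest adjusted p = 0.0887), though single members were called, such as 3 MLL fusion targets higher, and 1 NRF2 gene higher and 5 lower. For homologous recombination genes, p53 targets and B cell markers, the median, mean and test did not share a sign.

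The effects of 3-HF were then compared between lines, the contrast that the series title draws between MLL-rearranged and other AML. PRKDC differed: its mean effect in MOLM13 and MV411 lay -1.76 ± 0.27 (log2, SE) from that in U937, and MYC lay -2.44 ± 0.15 from it. MKI67 (-1.42 ± 0.27) was lower, and ITGAM (2.05 ± 0.24) and MEIS1 (0.58 ± 0.18) higher, relative to U937. The 2 lines did not agree for MKI67, which lay -3.22 ± 0.31 from U937 in MV411 and 0.39 ± 0.31 in MOLM13 (adjusted p = 0.413). For MEIS1 they were alike, at 0.59 ± 0.20 in MV411 (adjusted p = 0.0293) and 0.57 ± 0.21 in MOLM13 (0.0550, not called). TERT, the catalytic subunit of telomerase, lay -4.65 ± 0.21 and the endocytic adaptor gene REPS2 5.74 ± 0.54 from U937. Of 14196 genes, 2490 were higher and 2392 lower in the MLL-rearranged mean than in U937, 1331 and 1262 by at least 2-fold. edgeR's quasi-likelihood test of this difference gave adjusted p = 3.7e-05 for PRKDC, 5.7e-10 for MYC, 3.5e-04 for MKI67, 1.8e-06 for ITGAM and 0.0162 for MEIS1. MEIS1 lost the call without MV411 DMSO 2 (0.0515), MV411 3-HF 1 (0.0558), U937 DMSO 1 (0.0752) or U937 3-HF 2 (0.0581). MOLM13 was sampled at 12 h and U937 at 24 h, so a difference can come from time as well as from line. U937 was the only line without the rearrangement, so MLL status cannot be told apart from other differences between the lines.

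Several other large differences rest on genes with few counts in at least 1 of the 3 lines. The tetraspanning membrane gene MS4A14 (7.71 ± 1.28), the antisense gene CCR5AS (7.39 ± 1.84), the homeobox gene CDX2 (6.08 ± 1.897), the glucose transporter gene SLC2A14 (6.01 ± 0.95) and the noncoding LINC02801 (5.77 ± 1.62) were higher. VARS1 (-5.95 ± 1.68), an aminoacyl-tRNA synthetase counted at a low mean of 2.92 CPM, SLAMF8 (-5.64 ± 0.93), RHEX (-4.91 ± 1.55), FAM124A (-4.90 ± 0.68) and APOL4 (-4.52 ± 1.36) were lower. Against U937, CDX2 (adjusted p = 0.0850) and RHEX (0.0711) were not called for MOLM13 alone, nor APOL4 (0.0541) for MV411 alone. APOL4 lost its call without each U937 library but 3-HF 2 (adjusted p of 0.0712 to 0.129) and with no low-count filter (0.0581), and VARS1 without MV411 DMSO 1 (0.0510). RHEX lost it without MV411 DMSO 2 (1.00) or U937 3-HF 1 (0.0555), LINC02801 without MV411 3-HF 2 (1.00), CCR5AS without U937 DMSO 1 (0.0722) and CDX2 without U937 DMSO 2 (1.00). Among the 11181 genes that passed the count filter in each line, a restriction chosen after these values were seen, large positive differences included those of REPS2 (5.74 ± 0.53), the histone gene H2AC6 (5.57 ± 0.20), SDS (5.16 ± 0.48) and OAS1 (4.15 ± 0.47). Large negative differences included those of TERT (-4.64 ± 0.20), RGS16 (-4.23 ± 0.27), ETV4 (-4.18 ± 0.28) and SLC7A5 (-3.80 ± 0.21).

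Of 28 lists, fry called 20 for this difference, 7 up and 13 down, and 14 of these calls held with an estimated correlation. All 28 MYC and ribosome biogenesis genes and all 41 G1/S genes were lower relative to U937, also adjusted over the list alone, with medians of -1.65 and -1.81 (fry adjusted p = 3.8e-11 and 3.3e-14). Of 31 homologous recombination genes 22 were lower and of 20 checkpoint genes 13, the same counts adjusted over the list alone, with medians of -1.03 and -0.87 (fry adjusted p = 2.4e-07 and 1.2e-08). NHEJ factors had a median of -0.35 and a fry adjusted p = 0.0128, lost at adjusted p = 0.549 with an estimated correlation and without U937 DMSO 3 (0.0669). Interferon genes, 16 of 29 higher, and monocyte genes, 12 higher and 1 lower of 19, also adjusted over the list alone, had medians of 1.496 and 1.37 (fry adjusted p = 5.1e-09 and 3.8e-11). ATF4 genes (19 of 27 lower and 2 higher, 20 and 2 adjusted over the list alone, -1.27), heat shock genes (11 of 15, 11 adjusted over the list alone, -1.53), MAPK output genes (9 of 22, 11 adjusted over the list alone, -1.65) and FLT3 and STAT5 output genes (7 of 12, 7 adjusted over the list alone, -0.91) were lower relative to U937, with fry adjusted p = 6.1e-10, 1.5e-10, 5.5e-09 and 9.0e-09. For the mean of both lines, G2/M genes were lower in 25 of 31 (27 adjusted over the list alone, median -1.08), but only MV411 was lower (median -2.74). MOLM13 lay above U937, with 8 of 31 higher and 0 lower, also adjusted over the list alone, a median of 0.39 and a fry adjusted p = 0.00670, lost at adjusted p = 0.359 with an estimated correlation. Homologous recombination and checkpoint genes were lower in both lines by fry, and for MOLM13 the calls were lost with an estimated correlation (adjusted p = 0.334 and 0.196). The NHEJ, p53, NRF2 and B cell lists were called by fry for MV411 against U937 and not for MOLM13 (adjusted p = 0.556, 0.548, 0.461 and 0.0679). For MV411 against U937 fry called 21 of 28 lists, and camera with an estimated correlation called 12. In the mean, genes of the ER unfolded protein response were lower in 11 of 19 (12 adjusted over the list alone, median -0.65). Cholesterol synthesis genes were lower in 13 and higher in 1 of 23 (15 and 1 adjusted over the list alone, median -0.57). Lysosome genes were higher in 11 of 20 (13 adjusted over the list alone, median 0.67), with adjusted p = 0.0360 with an estimated correlation. The calls for p53 targets (median -0.10), the BCL2 family (0.13), NF-kB genes (0.47), NRF2 genes (0.05) and B cell markers (0.47) were lost with an estimated correlation, at adjusted p = 0.540, 0.464, 0.532, 0.663 and 0.663. The NF-kB call ended without MV411 DMSO 2 (0.103), MV411 DMSO 3 (0.0776), MV411 3-HF 1 (0.0874), MV411 3-HF 3 (0.0544) or U937 3-HF 3 (0.102), and the B cell call without MOLM13 DMSO 3 (0.0674), MOLM13 3-HF 3 (0.0549), MV411 DMSO 2 (0.0728), MV411 DMSO 3 (0.0656), MV411 3-HF 1 (0.0584), U937 DMSO 3 (0.0640) or U937 3-HF 1 (0.0616). The NRF2 call ended without MOLM13 DMSO 1 (0.0600), MOLM13 DMSO 2 (0.0610), MOLM13 3-HF 2 (0.0632), MOLM13 3-HF 3 (0.0549), MV411 DMSO 2 (0.148), MV411 DMSO 3 (0.233), MV411 3-HF 1 (0.174), MV411 3-HF 2 (0.0660), MV411 3-HF 3 (0.133), U937 DMSO 2 (0.0810), U937 DMSO 3 (0.0839), U937 3-HF 1 (0.0845), U937 3-HF 2 (0.0521) or U937 3-HF 3 (0.211), and with RLE scaling (0.0650). The NHEJ call ended under upper quartile scaling (0.0647). MLL fusion targets (-0.05 with a fry direction of up, adjusted p = 0.552) and MLL cofactors (-0.22, 0.135) were not called, though the cofactors were called without MV411 DMSO 1 (0.00752).

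MOLM13 and MV411 were compared with each other and for shared calls. Of 11743 genes tested in both, 2028 rose and 2463 fell in both, where independent lists of these sizes would share 786 and 999, and 140 moved in opposite directions, where 1774 would. The log2 fold changes correlated across genes at Pearson r = 0.73, genes not being independent, and the lines share no control libraries. Without MV411 DMSO 1, 2374 rose and 2727 fell in both and 308 went opposite ways (r = 0.69). The same correlation was 0.15 between MOLM13 and U937 and 0.22 between MV411 and U937. The U937 calls shared 0 genes with MOLM13 and 1 with MV411 in the same direction. In the opposite direction 5 and 9 were called, where independent lists give about 3.22 and 3.24 opposite. The balance turned round with the replicate block in U937: 616 genes were called in the same direction in U937 and MOLM13 and 232 in opposite directions, where independent lists give 368 and 359. For U937 and MV411 these were 640 and 191, against 359 and 347. PSAT1 fell in MOLM13 (-2.02 ± 0.14) and MV411 (-2.82 ± 0.13) and rose in U937, and H2AC6 rose by 2.53 and 4.98 in MOLM13 and MV411 and fell in U937.

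Between MOLM13 and MV411 the effect differed for 1033 genes in one direction and 1084 in the other, 631 and 640 by at least 2-fold. Relative to MV411, the effect in MOLM13 was higher for PRKDC (1.21 ± 0.31), MKI67 (3.61 ± 0.32) and CDKN1A (0.76 ± 0.25), and it was lower for MYC (-1.76 ± 0.17) and ITGAM (-2.41 ± 0.25). In that order, edgeR's quasi-likelihood test gave adjusted p = 0.00957, 1.1e-07, 0.0451, 3.3e-07 and 8.0e-07. G2/M genes were higher in 29 of 31 (30 adjusted over the list alone, median 2.98) and G1/S genes in 38 of 41 (39 adjusted over the list alone, median 2.02). Of 28 lists, fry called 18 for this difference, 9 up and 9 down, and 4 calls held with an estimated correlation: G2/M (adjusted p = 7.2e-07), G1/S (1.9e-08), homologous recombination (median 1.26, 0.00140) and checkpoint genes (median 0.64, 5.9e-04). Homologous recombination genes were higher in 20 of 31 (24 higher and 1 lower adjusted over the list alone) and checkpoint genes in 10 of 20 (13 adjusted over the list alone). In the other direction, MAPK output genes (median -0.92), interferon genes (-0.63) and monocyte genes (-0.11) were called lower by fry, at adjusted p = 8.7e-05, 2.2e-04 and 1.8e-06, and lost with an estimated correlation at 0.0731, 0.108 and 0.0731. The lower count went from 1084 to 727 without MV411 DMSO 2 and to 1602 without MV411 DMSO 1. Line and time of treatment cannot be told apart here.

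**Figure D1:**
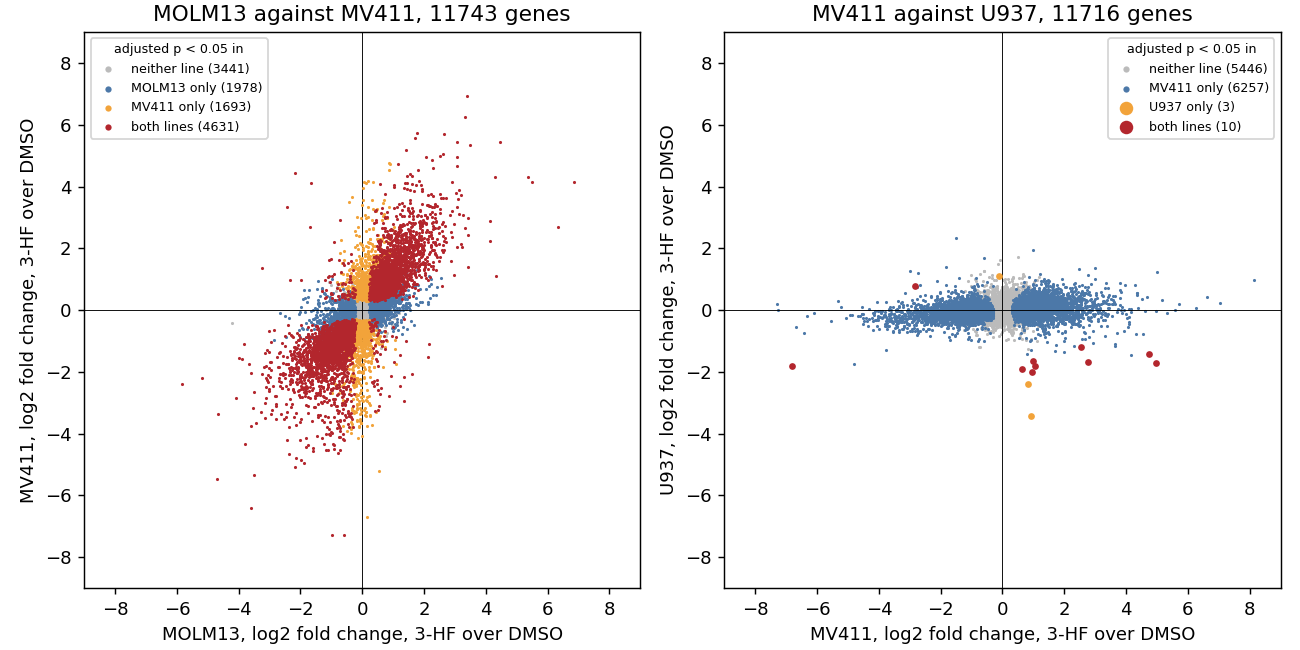
Log2 fold changes, 3-HF over DMSO, of genes tested in both lines, MOLM13 (x axis) against MV411 (y axis) over 11743 genes on the left and MV411 against U937 over 11716 genes on the right, with colors for the lines in which a gene was called. On the left 4631 genes were called in both lines, on the right 10, from fits without the replicate block. With the block in U937, 831 genes were called in both MV411 and U937, 640 in the same direction and 191 in opposite directions.

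**Figure D2:**
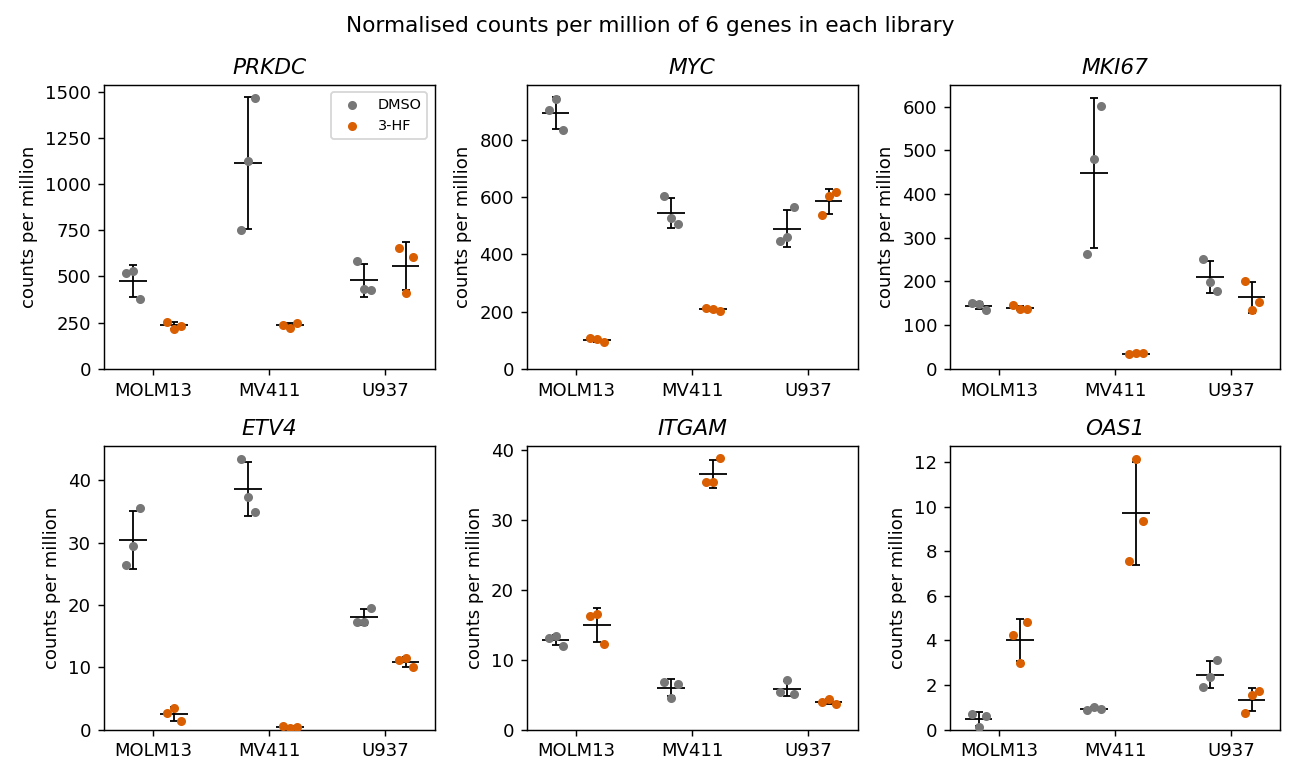
Normalised CPM (y axis) of PRKDC, MYC, MKI67, ETV4, ITGAM and OAS1 in each of the 18 libraries, by line (x axis) and treatment (color), 1 point per library, with bars for the mean and SD. PRKDC went from 476 ± 85.8 to 236 ± 19.8 CPM in MOLM13 and from 1117 ± 358 to 237 ± 11.4 CPM in MV411 (mean ± SD, n = 3).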

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

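Of the tests here, those of FLT3 signalling and of exit from the cell cycle were chosen after the result was seen. A test of the difference between lines picked each of the following. Counts of genes with a higher and a lower 3-HF effect were 1632 and 1656 for MOLM13 against U937, 2686 and 2534 for MV411 against U937, 2490 and 2392 for the MLL-rearranged mean against U937, and 1033 and 1084 for MOLM13 against MV411.

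Between the MLL-rearranged mean and U937, the log2 effects differed for PRKDC (-1.76 ± 0.27), MYC (-2.44 ± 0.15), MEIS1 (0.58 ± 0.18), MKI67 (-1.42 ± 0.27), ITGAM (2.05 ± 0.24), MS4A14 (7.71 ± 1.28), CCR5AS (7.39 ± 1.84), CDX2 (6.08 ± 1.897), SLC2A14 (6.01 ± 0.95), LINC02801 (5.77 ± 1.62), REPS2 (5.74 ± 0.54), VARS1 (-5.95 ± 1.68), SLAMF8 (-5.64 ± 0.93), RHEX (-4.91 ± 1.55), FAM124A (-4.90 ± 0.68), TERT (-4.65 ± 0.21) and APOL4 (-4.52 ± 1.36). Between MOLM13 and MV411 they differed for PRKDC (1.21 ± 0.31), MYC (-1.76 ± 0.17), CDKN1A (0.76 ± 0.25), MKI67 (3.61 ± 0.32) and ITGAM (-2.41 ± 0.25).

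Lists with a higher median effect in the MLL-rearranged mean than in U937 were the BCL2 family (0.13), monocyte (1.37), interferon (1.496), NF-kB (0.47), NRF2 (0.047), lysosome (0.67) and B cell genes (0.47). With an estimated correlation the BCL2 family (adjusted p = 0.464), NF-kB (0.532), NRF2 (0.663) and B cell (0.663) calls were lost. Lower were NHEJ (-0.35), homologous recombination (-1.03), checkpoint (-0.87), p53 (-0.10), MYC (-1.65), G2/M (-1.08), G1/S (-1.81), ATF4 (-1.27), ER unfolded protein response (-0.65), heat shock (-1.53), cholesterol (-0.57), FLT3 and STAT5 (-0.91) and MAPK output genes (-1.65). With an estimated correlation the NHEJ (0.549) and p53 (0.540) calls were lost, and for G2/M genes MOLM13 on its own lay above U937 (0.39, fry adjusted p = 0.00670, lost at adjusted p = 0.359 with an estimated correlation) and MV411 below it (-2.74). The MKI67 difference was likewise 0.39 ± 0.31 for MOLM13 (adjusted p = 0.413) and -3.22 ± 0.31 for MV411. MOLM13 lay above MV411 for NHEJ (0.24), homologous recombination (1.26), checkpoint (0.64), p53 (0.35), G2/M (2.98), G1/S (2.02), ATF4 (0.63), heat shock (0.47) and metallothionein genes (0.70). Of these, with an estimated correlation, the NHEJ (0.271), p53 (0.238), ATF4 (0.108), heat shock (0.108) and metallothionein (0.373) calls were lost. It lay below MV411 for MYC (-0.18), monocyte (-0.11), myeloid progenitor (-0.68), interferon (-0.63), NF-kB (-0.26), NRF2 (-0.26), ER unfolded protein response (-0.21), cholesterol (-0.34) and MAPK output genes (-0.92), and with an estimated correlation each of these 9 calls was lost (adjusted p of 0.0731 to 0.485).

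Few genes were called in U937. Lower depth is argued against by the totals, 8.60 to 10.1 M in U937 and 8.64 to 9.99 M in MOLM13. Thinning MOLM13 to the smallest U937 total thus removed little, and 6774 genes were still called. A swap of U937 libraries would let another split call many genes, and the most was 13 without the block. That fit called only 14 genes for the real split, so it could hide a swap. With the block, the other splits that part all same-number pairs called 0. A shared replicate day that hides the effect remains a candidate explanation for part of the gap, since 1379 genes were called with the replicate number as a block. With the same block 6886 genes were called in MOLM13 and 6804 in MV411, so it does not close the gap. Changes were also smaller in U937. The SD of log2 fold changes over genes was 0.28, against 0.86 in MOLM13 and 1.27 in MV411, and the blocked changes had a median size of 0.36. The values thus show a weaker response in these U937 libraries, and its cause was not tested.

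In MV411, DMSO 1 stands apart from the other DMSO libraries. Exposure to 3-HF is argued against by an r of -0.15 across genes, which are not independent, with the effect in MOLM13. RNA from MOLM13 gave a median of 0% of the MOLM13 level, but over 4 genes, too few to decide. GC content and length took 31.0% of the variance of its log2 ratio, between the limits set for either reading, so this could be part of the cause. No biological explanation was tested.

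The MAPK and STAT5 output lists were called lower by fry in MOLM13 and MV411, though 5 of 20 MAPK genes rose in MV411. With an estimated correlation the MAPK call in MOLM13 held (adjusted p = 0.0290), and the STAT5 call in MOLM13 (0.0511) and the MAPK (0.0564) and STAT5 calls in MV411 (0.115) were lost. A general loss of short-lived transcripts is argued against, since these had medians of 0.24 or more in both lines. Exit from the cell cycle stays open in both lines. In MOLM13 the G2/M list stood at -0.053 while the G1/S list fell to -1.04, so the values point both ways, and in MV411 the lists stood at -3.23 and -2.78. Loss of signalling by FLT3, known from earlier work to be mutated in both lines, also stays open. Its test, with -1.57 as the highest of 4 medians after genes shared with other lists were left out, decides nothing: it used the genes of the pattern, and no gene left the MAPK list. MLL status and every other difference from U937 are confounded with it, and phosphorylated FLT3 and STAT5 after 3-HF would test it.

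For the counts within a line, the 10 splits of 6 libraries are too few to judge chance. The real split, 1 of 10 as large in each line, called 6840 genes in MOLM13 (highest other 0), 7048 in MV411 (0) and 14 in U937 (13). The U937 split with 13 genes set DMSO 1, 3-HF 1 and 3-HF 3 against the rest and parted 1 of the 3 same-number pairs of libraries. Of the 4 U937 splits that part all 3 pairs, the real split called 14 genes and the others 0, and with the replicate number as a block 1379 and 0, though 4 splits are too few to judge chance as well. Of 100 relabelings of treatment within lines, the real labels among them, 2 gave as many genes for MOLM13 against U937 (highest other 4382). The count was 2 for MV411 against U937 (5743) and 2 for the MLL-rearranged mean against U937 (5816). For MOLM13 against MV411 it was 9 (5448). Treatment was relabeled in every line at once, so these counts ask whether 3-HF acts in any line. They do not test equal effects between lines, so chance cannot be excluded by them for any of these differences. These fits ran without robust weighting, where the real labels gave 3299, 5238, 4909 and 2135 genes. The other relabelings that call as many genes as the real labels leave a compared line unmixed or wholly exchanged, a structure of the samples, so they carry the treatment effect of that line. For MOLM13 against MV411, the 75 relabelings that mixed both lines called 0 genes.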

How the results depend on the processing

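Upper quartile scaling of the lists, the restriction of differences to filtered genes and the overlap without MV411 DMSO 1 were tests chosen after the data were seen. With upper quartile scaling the MOLM13 medians of NHEJ factors (0.12) and MLL cofactors (0.016) turned positive. U937 counts moved most: 9 higher and 32 lower (2 higher by at least 2-fold) with all libraries in a single fit, 11 and 31 (2) with DESeq2, 1 higher with RLE scaling, and 16 and 40 (6 and 21 by at least 2-fold) with no filter. With the replicate number as a block they were 585 and 794 (25 and 24), and leaving out a library gave 0 to 2 and 6 to 17 (0 to 1 and 6 to 16). For the other lines, leaving out a library gave 2761 to 3626 higher and 3017 to 3855 lower in MOLM13 and 2771 to 4751 and 2660 to 4711 in MV411. The calls shared by MOLM13 and MV411 were 1319 higher, with 41 opposite, at an adjusted p under 0.01, and 737 higher, 844 lower and 18 opposite at 2-fold. Without MV411 DMSO 1, 308 were opposite. With the block, list calls lost in MOLM13 were MLL targets (adjusted p = 0.0998 by fry), MLL cofactors, AhR targets, oxidative phosphorylation and metallothionein genes, and in MV411 MLL targets (0.139), the BCL2 family, AhR targets and NRF2 genes. The cause was not tested.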

Other observations

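The test of the histone genes was chosen after the result was seen. Canonical histone genes, whose transcripts mostly lack a poly(A) tail, had a median log2 fold change of 1.36 in MOLM13 (11 of 16 higher, 11 adjusted over the list alone), 1.95 in MV411 (11 higher and 2 lower of 16, 12 and 2 adjusted over the list alone) and -1.01 in U937 (3 of 17 lower, 9 adjusted over the list alone). With the replicate number as a block, 9 of the 17 were lower in U937, at a median of -1.01. Directions were kept with RLE (1.35, 1.96 and -1.01) and upper quartile scaling (1.52, 2.13 and -0.99). The fry p was 3.5e-04, 2.6e-04 and 0.00303, and camera with an estimated correlation gave 0.0993, 0.0892 and 0.00331. A change in histone transcript tailing could give this shift, and the U937 median of -1.01 goes the other way from the other lines. Libraries made without poly(A) selection would test it. Copies of these genes share reads, so single members are uncertain.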
